A study of Homo sapiens with 42 samples.

How the data were processed

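Gene-level RNA-seq values of 42 libraries were analysed. They came from the lung cancer cell lines HCC366 (adenosquamous, non-small cell) and NCI-H1650 (adenocarcinoma), written H1650 here, in which genes were cut with CRISPR-Cas9. At day 7 each line had 6 control libraries, 3 with a guide to the AAVS1 locus, a common cutting control, and 3 with a guide labelled Chr2.2, and 6 XRN1 knockout libraries, 3 for each of 2 guides. A further 18 HCC366 libraries carried pairs of guides, with 3 control, 6 XRN1 knockout, 3 PKR knockout and 6 PKR and XRN1 knockout libraries, and their labels give no day. By their labels all PKR knockout libraries carried the same PKR guide, and all 3 controls the same guide pair. Other effects of that PKR guide cannot be told apart from PKR loss. PKR is the protein made by EIF2AK2. Groups and replicate numbers were taken from the sample titles. In the guide-pair titles the number follows the word Media, which the labels do not explain, and it was taken as the replicate number. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

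The authors deposited 1 table per library with RSEM expected counts, TPM and FPKM for 60662 genes. Per the submitters' processing notes, reads were handled with FastQC 0.11.9, cutadapt 2.8, STAR 2.7.5b and RSEM against hg38, with no RSEM version. The annotation release, library kit and strandedness are not given in the sources used here, so reads of a gene and an antisense or overlapping gene, or of near-identical copies, could have been divided between them. The expected counts were deposited without normalization, and 91.9% to 94.3% of a library's values were whole numbers (at least 80.9% of those above 0). They were rounded to whole numbers before testing. The deposited TPM, scaled by the authors to the same total in every library after dividing by effective length, served for an alternative test. The FPKM values were not used. Gene symbols were found for 60402 identifiers, and 58489 identifiers, compared without their version, matched GENCODE 29 (GRCh38), from which coordinates and gene types were taken. Replicate pairs of 1 guide differed by more than sampling noise in all 42 pairs (chi-square over degrees of freedom 5.23 to 292.63, genes with 20 or more counts), so none was treated as a duplicate.

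Counts were tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood F tests (glmQLFit and glmQLFTest) after TMM normalization and filterByExpr, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values of genes come from this test. Each day-7 line was fitted alone for its XRN1 effect. All 24 day-7 libraries were fitted together for the difference between the lines, and all 18 guide-pair libraries for the PKR comparisons. Fold changes are log2 with a standard error (SE), equal to the fold change divided by the square root of F. Levels are CPM, counts scaled to library size with TMM factors, given as mean ± SD over libraries.

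The 24 gene lists were written before the data were examined, as were the design, the named-gene rule and the first set of alternatives. They cover interferon-stimulated genes, double-stranded RNA sensing, interferon genes, NF-kB and inflammatory genes, ATF4 stress response genes, ER chaperones, decapping and 5' to 3' decay, deadenylation, the exosome, factors of nonsense-mediated decay (NMD), NMD-sensitive transcripts, immediate-early and other unstable mRNAs, cell cycle, p53 targets, MHC class I presentation, cholesterol synthesis, hypoxia and glycolysis, ribosomal proteins, mitochondrially encoded genes, replication histones, and markers of lung adenocarcinoma epithelium, squamous or basal epithelium, mesenchymal cells, and immune or endothelial cells. The lists overlap: 7 genes of the sensing list (IFIH1, RIGI, DHX58, EIF2AK2 and OAS1 to OAS3) are also interferon-stimulated, and ATF3 and ATF4 are in both the ATF4 and the NMD-sensitive list. Lists with at least 5 tested members were tested against all other genes with camera (limma 3.58.1) and a preset correlation between genes of 0.01. The test was repeated with an estimated correlation, and adjustment was over the lists within a comparison.

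The text names XRN1 and EIF2AK2, and the 8 highest and 8 lowest fold changes per comparison among genes with a symbol that is no clone name, an adjusted p under 0.05, a mean CPM of at least 5, the same direction with each XRN1 guide, and groups that do not overlap. It also names, for each list past the test, the 3 members with the lowest adjusted p in the list's direction, and 4 members of the interferon and ATF4 lists in either direction. For differences between effects, 5 genes per direction were taken without the overlap condition. Not all genes that the rule takes are printed, and the interferon genes themselves were added after their values were seen.

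Whether replicate numbers pair the libraries was checked by correlating deviations from group means across genes. In HCC366 at day 7, all 18 pairs with the same number correlated above 0.1 (0.333 to 0.648, median 0.407, against a median of -0.288 for different numbers), so the numbers pair these libraries. The labels do not say what a number stands for. The fit with the number as a block is given beside results of these libraries where it changed a call. In the other sets not every pair passed 0.1, but every library correlated best with its own number, so a pairing is not excluded there.

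Alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors in edgeR, limma-trend on log2(TPM + 1) for genes with a mean TPM of at least 1, no filter, a filter of 50 counts, a 2-fold minimum, the replicate block, 1 XRN1 guide or 1 control guide at a time, smaller or larger sets of libraries in the fit, and leaving out each library. Fits within single replicate numbers of HCC366 at day 7, and the block combined with DESeq2 factors or an estimated correlation, were added after the data were seen. Deposited TPM raised the median of all tested genes over the TMM value by 0.20 (HCC366, day 7), 0.058 (H1650), 0.21 (guide pairs, PKR intact) and 0.29 (PKR knocked out) on the log2 scale, and lowered it by 0.18 for the difference between lines and by 0.38 for the control lines. Directions in the results are those under TMM.

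The procedure was tested on simulated counts with 200 changed genes, as many raised as lowered. The simulation drew genes independently, without replicate numbers, and changed far fewer genes than passed in most comparisons. Its shares are therefore only a guide to recovery in the data. For HCC366 at day 7 (14352 genes) it recovered 43.3% of 1.5-fold, 83.6% of 2-fold and 93.9% of 4-fold changes. In H1650 (16320 genes) the shares were 61.2%, 88.1% and 93.9%. For XRN1 knockout with PKR intact (16619 genes) they were 68.7%, 77.6% and 86.4%. The PKR knockout alone, 3 against 3 libraries (16597 genes), gave 52.2%, 76.1% and 77.3%. The difference of the XRN1 effect between PKR backgrounds (16626 genes) gave 52.2%, 64.2% and 72.7%, and that between lines (17522 genes) gave 28.4%, 56.7% and 95.5%. Results for some single genes are not reported here. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.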

Results

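RNA was sequenced from lung cancer cells after CRISPR-Cas9 knockout of XRN1, the gene of the main cytoplasmic 5' to 3' exoribonuclease, and of EIF2AK2, the gene of the double-stranded RNA-activated kinase PKR. HCC366 and H1650 cells were each profiled at day 7 in 6 control and 6 XRN1 knockout libraries. In HCC366 cells with pairs of guides there were 3 control, 6 XRN1 knockout, 3 PKR knockout and 6 PKR and XRN1 knockout libraries. All libraries with PKR knocked out shared the same PKR guide. The series title names XRN1 deletion, PKR-dependent lethality and interferon-activated cells, so the comparisons ask what XRN1 loss does in each line and how much of it needs PKR. Total expected counts per library were 8433991 to 25669941 in HCC366 and 11136668 to 28689471 in H1650 at day 7, and 14138953 to 20444109 in the guide-pair set.

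The targeted transcripts were examined first. XRN1 (ENSG00000114127.10, chromosome 3, 142306607 to 142448062 on the minus strand, GRCh38) was still present as RNA in every knockout group. Its level was 47.9 ± 2.48 CPM in HCC366 controls and 45.1 ± 4.20 CPM in knockouts (SD, n = 6 each), a difference within the spread (log2 -0.090, SE 0.072, adjusted p = 0.313; 0.14 on the TPM scale). In H1650 it was 54.8 ± 1.81 and 59.2 ± 7.45 CPM (n = 6 each; log2 0.11, adjusted p = 0.241). In the guide-pair set XRN1 RNA was higher after XRN1 knockout with PKR intact, at 72.0 ± 4.88 CPM (n = 6) against 55.1 ± 3.12 CPM (n = 3; log2 0.39, SE 0.071, adjusted p = 4.38e-05). With PKR knocked out it was 62.4 ± 5.07 CPM (n = 6) against 61.0 ± 2.12 CPM (n = 3, adjusted p = 0.757), and the difference of these effects was -0.35 (SE 0.099, adjusted p = 0.00827). An edited transcript can still be made and counted, so these levels do not check the loss of XRN1. EIF2AK2 (ENSG00000055332.18, chromosome 2, 37099210 to 37157065 on the minus strand, GRCh38) was lower in PKR knockout libraries, at 177 ± 12.1 against 288 ± 16.9 CPM with XRN1 intact (n = 3 each; log2 -0.70, SE 0.11, adjusted p = 0.0354, not past the threshold in 9 of 18 fits without 1 library), and at 456 ± 54.0 against 881 ± 118 CPM with XRN1 knocked out (n = 6 each; log2 -0.95, SE 0.079, adjusted p = 3.75e-10).

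XRN1 knockout in HCC366 at day 7 was accompanied by higher levels of antiviral and inflammatory genes. Of 48 tested interferon-stimulated genes, 44 rose, none fell and 4 did not pass, with a median log2 fold change of 1.95 (camera adjusted p = 4.41e-13). This list call was lost with the members' own correlation (adjusted p = 0.298 with an estimated correlation). HELZ2, a transcriptional coactivator, rose from 76.3 ± 19.8 to 836 ± 319 CPM (log2 3.45, SE 0.26, adjusted p = 7.76e-08). IRF7, the transcription factor that drives type I interferon production, rose from 10.5 ± 2.8 to 119 ± 66.9 CPM, and IRF9, the DNA-binding part of the ISGF3 complex, from 5.74 ± 1.81 to 58.1 ± 13.9 CPM. EIF2AK2 is in this list and rose by 1.17 (SE 0.15). IFNB1, the gene of interferon beta, was too low for the filter, at 0.051 ± 0.064 CPM in controls and 1.25 ± 0.869 CPM in knockouts (n = 6 each), and IFNL1, the single interferon gene tested, rose by 3.23. Of 21 genes of double-stranded RNA sensing, 12 rose and 3 fell (median 0.57, camera adjusted p = 0.00103, adjusted p = 0.213 with an estimated correlation). TICAM1, the adaptor of Toll-like receptor 3, rose by 0.57 (SE 0.056). NF-kB and inflammatory genes rose together, 26 of 27 (median 1.44, camera adjusted p = 1.98e-21), and this call held with an estimated correlation (adjusted p = 0.0158). The adaptor gene TRAF1 went from 59.7 ± 10 to 400.5 ± 55.0 CPM, and CXCL2, a neutrophil chemokine, from 34.0 ± 7.40 to 243 ± 26.7 CPM.

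Stress response genes moved in the same knockout cells. In the ATF4 list 23 of 38 members rose and 5 fell (median 0.34, camera adjusted p = 3.77e-07, adjusted p = 0.103 with an estimated correlation). The stress-induced factor ATF3 rose from 17.5 ± 2.57 to 182 ± 33.3 CPM (log2 3.37, SE 0.13, adjusted p = 2.71e-10). PPP1R15A (GADD34), which directs dephosphorylation of eIF2α, rose by 2.36 (SE 0.098), the pro-apoptotic factor DDIT3 (CHOP) by 2.71 (SE 0.18), and the pseudokinase TRIB3 by 2.11 (SE 0.13). Of 20 ER chaperone genes 14 fell and 3 rose (median -0.40, camera adjusted p = 0.0151, adjusted p = 0.423 with an estimated correlation), among them the disulfide isomerase PDIA4 (-0.76, SE 0.11). NMD-sensitive transcripts rose in 18 of 22 cases with none falling (median 0.79, camera adjusted p = 2.84e-12), and the call held with an estimated correlation (adjusted p = 0.00114). SNHG12, a host RNA of small nucleolar RNAs, rose from 15.8 ± 2.15 to 68.0 ± 8.70 CPM. Of 32 immediate-early and unstable mRNAs, 25 rose and 1 fell (median 0.80, camera adjusted p = 8.79e-12, adjusted p = 0.0323 with an estimated correlation), with TXNIP up by 2.47 (SE 0.11). Of 23 p53 targets 9 rose and 2 fell (median 0.18, camera adjusted p = 0.00744, adjusted p = 0.0515 with an estimated correlation), including CDKN1A, the cell cycle inhibitor p21 (1.22, SE 0.11).

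Several gene lists fell. In the cell cycle list 33 of 35 members were lower and 1 was higher (median -0.69, camera adjusted p = 2.37e-16). That call held with an estimated correlation (adjusted p = 0.0214) but not when the replicate number was also a block (adjusted p = 0.067 with an estimated correlation). CENPF, a kinetochore protein, fell from 428 ± 13.9 to 206 ± 14.6 CPM (log2 -1.05, SE 0.060). Ribosomal protein mRNAs were lower in 72 of 73 cases (median -0.65, camera adjusted p = 4.91e-23, adjusted p = 0.0957 with an estimated correlation), for example RPSA (-0.84, SE 0.057). Among 23 cholesterol synthesis genes 18 fell and 1 rose (median -0.60, camera adjusted p = 2.78e-05, adjusted p = 0.28 with an estimated correlation). Replication histone genes fell in 16 of 21 cases (median -0.54, camera adjusted p = 1.85e-05, adjusted p = 0.196 with an estimated correlation), and mitochondrially encoded genes in 9 of 13 (median -0.60, camera adjusted p = 0.0141, adjusted p = 0.536 with an estimated correlation). The machinery lists did not pass the test: decapping and 5' to 3' decay had 8 higher and 11 lower of 23 (median -0.21; 0.021 on the TPM scale), deadenylation 5 and 3 of 19 (median 0.092), the exosome 2 and 7 of 18 (median -0.18; 0.028 on the TPM scale) and NMD factors 7 and 3 of 14 (median 0.21). Neither did MHC class I presentation (7 higher, 2 lower of 16), hypoxia and glycolysis (3 and 5 of 17, median 0.12 with a camera direction down), mesenchymal markers (4 and 1 of 10) or lung epithelial markers (1 and 2 of 8). Of 4 tested squamous markers 3 rose. Immune and endothelial markers rose in 4 of 5 cases (camera adjusted p = 0.0044, adjusted p = 0.0515 with an estimated correlation), with ITGAM, an integrin of myeloid cells, at 4.17 ± 0.626 and 31.3 ± 4.78 CPM. Adjusted over the list alone, the counts of members higher and lower equalled those over all genes except for 24 higher in the ATF4 list, 12 lower in the decapping list, 4 higher in deadenylation, 8 higher in NMD factors, 19 higher and 1 lower among NMD-sensitive transcripts, and 73 lower among ribosomal proteins.

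Among the highest fold changes by the naming rule were those of DNAH3, an axonemal dynein heavy chain (0.584 ± 0.293 to 19.7 ± 6.91 CPM; log2 5.0, SE 0.32, adjusted p = 1.52e-08), DNAH12 and NID1, a basement membrane protein (4.63, SE 0.26). SLC12A7, a potassium-chloride cotransporter, rose from 7.58 ± 1.77 to 154 ± 28.5 CPM. The lowest was CPA4, a carboxypeptidase, at 213 ± 59.9 and 42.8 ± 17.3 CPM (log2 -2.31, SE 0.27, adjusted p = 5.02e-06). In all, 7816 of 14565 tested genes passed the threshold, 4008 higher and 3808 lower, of which 1501 were at least 2-fold higher and 98 at least 2-fold lower. Pseudogenes were more often higher (207 of 502) than lower (51), with a median of 0.35. On the TPM scale the split was 2306 higher and 235 lower.

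Libraries of HCC366 at day 7 fell into technical sets by replicate number. Mean fragment lengths were 226 to 248 bases in numbers 1 and 2 and 297 to 307 bases in number 3, and ribosomal RNA took 1.70% to 4.55% of counts in numbers 1 and 2 and at most 0.014% in number 3. Number 1 also stood apart from number 2. The 10 genes with the most counts took 13.93% to 22.2% of counts in number 1 and 7.36% to 9.24% in number 2. Protein-coding genes took 77.02% to 85.15% and 88.74% to 90.58%. Each number held both control and both XRN1 guides, so effects were recomputed within numbers 1, 2 and 3 in that order. The counts of genes past the threshold were 7431, 8080 and 8378. The median log2 fold changes were 2.65, 1.66 and 1.48 for interferon-stimulated genes, 0.78, 0.62 and 0.49 for RNA sensing, 1.78, 1.25 and 1.24 for NF-kB genes, 0.52, 0.29 and 0.45 for ATF4 genes, 0.77, 0.75 and 0.82 for NMD-sensitive transcripts and 0.97, 0.72 and 0.82 for immediate-early genes. They were -0.68, -0.71 and -0.74 for the cell cycle, -0.67, -0.70 and -0.63 for ribosomal proteins, -0.47, -0.64 and -0.73 for cholesterol synthesis, -0.78, -0.45 and -0.48 for histones and -0.42, -0.68 and -0.77 for mitochondrially encoded genes. ER chaperones gave -0.40, -0.45 and -0.37, with the last not past the test (camera adjusted p = 0.0527). The p53, marker and machinery lists were not recomputed within numbers.

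In H1650 at day 7, XRN1 knockout was accompanied by higher interferon genes and smaller shifts in most of these lists. All 4 tested interferon genes rose, with IFNB1 at 2.37 ± 0.815 and 9.77 ± 2.52 CPM (n = 6 each; log2 2.10, SE 0.20, adjusted p = 1.96e-06). Interferon-stimulated genes rose in 15 of 51 cases and none fell (median 0.35, camera adjusted p = 0.0068, adjusted p = 0.801 with an estimated correlation). With the replicate block the list passed (median 0.385, camera adjusted p = 3.06e-13, adjusted p = 0.206 with an estimated correlation as well). In fits with no block it did not pass without replicate 3 of either control guide (camera adjusted p = 0.0522 without that of Chr2.2, with a median of 0.23, and 0.0501 without the other). The Chr2.2 library held 0.309% ribosomal RNA against at most 0.01% in the other controls. DHX58 (LGP2), a RIG-I-like receptor, rose from 15.5 ± 2.76 to 35.1 ± 4.74 CPM. The RNA sensing list as a whole did not pass (6 higher, 2 lower of 21, camera adjusted p = 0.118), but did with the replicate block (camera adjusted p = 0.00236, adjusted p = 0.198 with an estimated correlation as well). NF-kB genes rose in 16 of 24 cases (median 0.48, camera adjusted p = 0.000175, adjusted p = 0.552 with an estimated correlation), such as the inhibitor NFKBIE (1.05, SE 0.14). The ATF4 list had 26 higher and 2 lower of 42 (median 0.28, camera adjusted p = 1.19e-07, adjusted p = 0.293 with an estimated correlation). ATF4 itself rose from 289 ± 13.9 to 387 ± 14.8 CPM (log2 0.42, SE 0.044) and CHAC1, a glutathione-degrading enzyme, by 0.91 (SE 0.092). NMD-sensitive transcripts were higher in 19 of 22 cases (median 0.68, camera adjusted p = 6.01e-16, adjusted p = 0.154 with an estimated correlation), with SNHG12 up by 1.85 (SE 0.13). Immediate-early genes rose in 12 of 33 cases (median 0.22, camera adjusted p = 0.0226, adjusted p = 0.552 with an estimated correlation; median 0.122 without replicate 2 of the AAVS1 control).

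Cell cycle genes fell in 28 of 35 cases in H1650 (median -0.29, camera adjusted p = 1.42e-11, adjusted p = 0.154 with an estimated correlation), for example KIF20A, a mitotic kinesin (-0.47, SE 0.056). Ribosomal protein mRNAs fell in 64 of 73 (median -0.28, camera adjusted p = 4.74e-17, adjusted p = 0.20 with an estimated correlation) and ER chaperones in 14 of 20 (median -0.30, camera adjusted p = 3.84e-05, adjusted p = 0.154 with an estimated correlation). Mitochondrially encoded genes fell in 12 of 13 (median -0.66, camera adjusted p = 0.000614, adjusted p = 0.592 with an estimated correlation) and cholesterol synthesis genes in 12 of 23 (median -0.21, camera adjusted p = 0.0149, adjusted p = 0.603 with an estimated correlation). CPT1B, a mitochondrial fatty acid importer, had one of the highest fold changes by the naming rule (8.87 ± 1.73 to 39.2 ± 2.17 CPM; log2 2.16, SE 0.11). SULT1A3, LRP5L, TBC1D3L and NPIPB15 were also among the 8 highest, and as members of multi-copy families their counts are uncertain. The lowest by that rule was MFAP5, a microfibril protein, at 55.8 ± 7.96 and 33.6 ± 6.63 CPM. In all, 5780 of 16506 tested genes passed, 3044 higher and 2736 lower, of which 455 were at least 2-fold higher and 15 at least 2-fold lower. On the TPM scale 1281 were higher and 57 lower.

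The difference between the lines was tested directly. The XRN1 effect on interferon-stimulated genes was lower in H1650 for 36 of 52 members and higher for none (median difference -1.63, camera adjusted p = 2.58e-19, adjusted p = 0.22 with an estimated correlation, 0.0299 with the replicate block as well). IRF9 went from 5.93 to 58.8 CPM in HCC366 and from 40.5 to 56.5 CPM in H1650 (log2 difference -2.83, SE 0.23, adjusted p = 3.73e-09). OAS2, an oligoadenylate synthetase, went from 3.69 to 66.8 CPM in HCC366 and was 300.4 and 334 CPM in H1650. EIF2AK2 had a log2 difference of -1.07 (SE 0.21). NF-kB genes had a smaller effect in H1650 for 18 of 28 (median -0.97, camera adjusted p = 1.02e-16, adjusted p = 0.0148 with an estimated correlation), and RNA sensing genes for 10 of 21 (median -0.47, camera adjusted p = 0.000423, adjusted p = 0.22 with an estimated correlation, 0.0296 with the block as well). For ATF4 genes 14 of 42 were lower and 3 higher (median -0.16, camera adjusted p = 0.000265, adjusted p = 0.265 with an estimated correlation). For p53 targets 7 of 23 were lower and 1 higher (median -0.28, camera adjusted p = 0.0106, adjusted p = 0.0529 with an estimated correlation, 0.0296 with the block as well). The immediate-early list differed for 15 of 33 (median -0.59, camera adjusted p = 3.92e-12, adjusted p = 0.0129 with an estimated correlation). The effect on cell cycle genes was higher in H1650, that is less negative, for 27 of 35 (median 0.47, camera adjusted p = 2.76e-16, adjusted p = 0.0129 with an estimated correlation), and on ribosomal protein genes for 51 of 73 (median 0.39, camera adjusted p = 2.69e-17, adjusted p = 0.192 with an estimated correlation). Among named genes detected in every group, NID1 had the lowest difference (-4.96, SE 0.24, adjusted p = 1.39e-13).

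Over all genes the XRN1 effect differed between lines for 4221 of 17905, 2154 higher and 2067 lower in H1650, and for 6921 (3835 and 3086) with the replicate block. On the TPM scale 632 passed, 35 higher and 597 lower, and with XRN1 guide 1 alone 1780. Within HCC366 numbers 1, 2 and 3 the count was 2944, 3711 and 2701, the interferon median -2.30, -1.49 and -1.07, and the ATF4 median -0.28, -0.034 and -0.15, of which the second did not pass (camera adjusted p = 0.0733). The NF-kB median was -1.38, -0.68 and -0.86, the immediate-early median -0.74, -0.40 and -0.71, the cell cycle median 0.44, 0.46 and 0.48 and the ribosomal protein median 0.41, 0.48 and 0.33. Across 13734 genes the fold changes of the lines correlated with Pearson r = 0.63 and Spearman rho = 0.678, and genes are not independent replicates. In both lines 1929 genes were higher, against 730.9 for independent lists, 1949 were lower against 715.9, and 98 went opposite ways against 1447.

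Before XRN1 loss the lines differed in interferon-stimulated genes. In controls 50 of 52 were higher in H1650 and 1 was lower (median 3.06, camera adjusted p = 5.05e-06, adjusted p = 0.948 with an estimated correlation; 2.95, 3.51 and 2.85 within HCC366 numbers 1, 2 and 3). MX1, an antiviral GTPase, had 3.02 CPM in HCC366 controls and 844 CPM in H1650 controls (log2 7.96, SE 0.45, adjusted p = 6.48e-15), and OASL, an oligoadenylate synthetase-like protein, 1.19 and 272 CPM. ATF4 genes were higher in H1650 for 28 of 42 and lower for 8 (median 0.71, 0.11 on the TPM scale; camera adjusted p = 0.000875, adjusted p = 0.649 with an estimated correlation; 0.86, 0.78 and 0.46 within numbers). NF-kB genes were lower in H1650 for 24 of 28 (median -2.60, camera adjusted p = 2.69e-09, adjusted p = 0.181 with an estimated correlation; -2.40, -2.67 and -2.82 within numbers). TNF had 79.6 CPM in HCC366 and 0.441 CPM in H1650 controls, and CCL20, a lymphocyte chemokine, 240 and 0.885 CPM. Markers of squamous epithelium were higher in H1650 for 12 of 13 (camera adjusted p = 1.69e-11, adjusted p = 0.0115 with an estimated correlation), for example KRT6A at 0.207 and 58.0 CPM, and lung epithelial markers for 11 of 12 (camera adjusted p = 1.75e-07, adjusted p = 0.127 with an estimated correlation, 0.0024 with the block), for example EPCAM at 0.787 and 140.5 CPM. MAGEA4, a cancer-testis antigen, was lower in H1650 (291 and 0.290 CPM). Of 17905 genes, 13972 differed (7217 higher, 6755 lower; 2526 and 6394 on the TPM scale; 13307, 13903 and 14068 within numbers). ER chaperones, MHC class I and mesenchymal lists did not pass (camera adjusted p = 0.0626, 0.523 and 0.523), but did with the replicate block (0.0337, 0.0247 and 0.0313; adjusted p = 0.78, 0.78 and 0.18 with an estimated correlation as well). ER chaperones also passed within each HCC366 number (medians -0.351, -0.338 and -0.465, camera adjusted p = 0.0088, 0.0368 and 0.00981), and without replicate 3 of the H1650 Chr2.2 control or of HCC366 XRN1 guide 1. Line and culture set cannot be separated here.

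**Figure D1:**
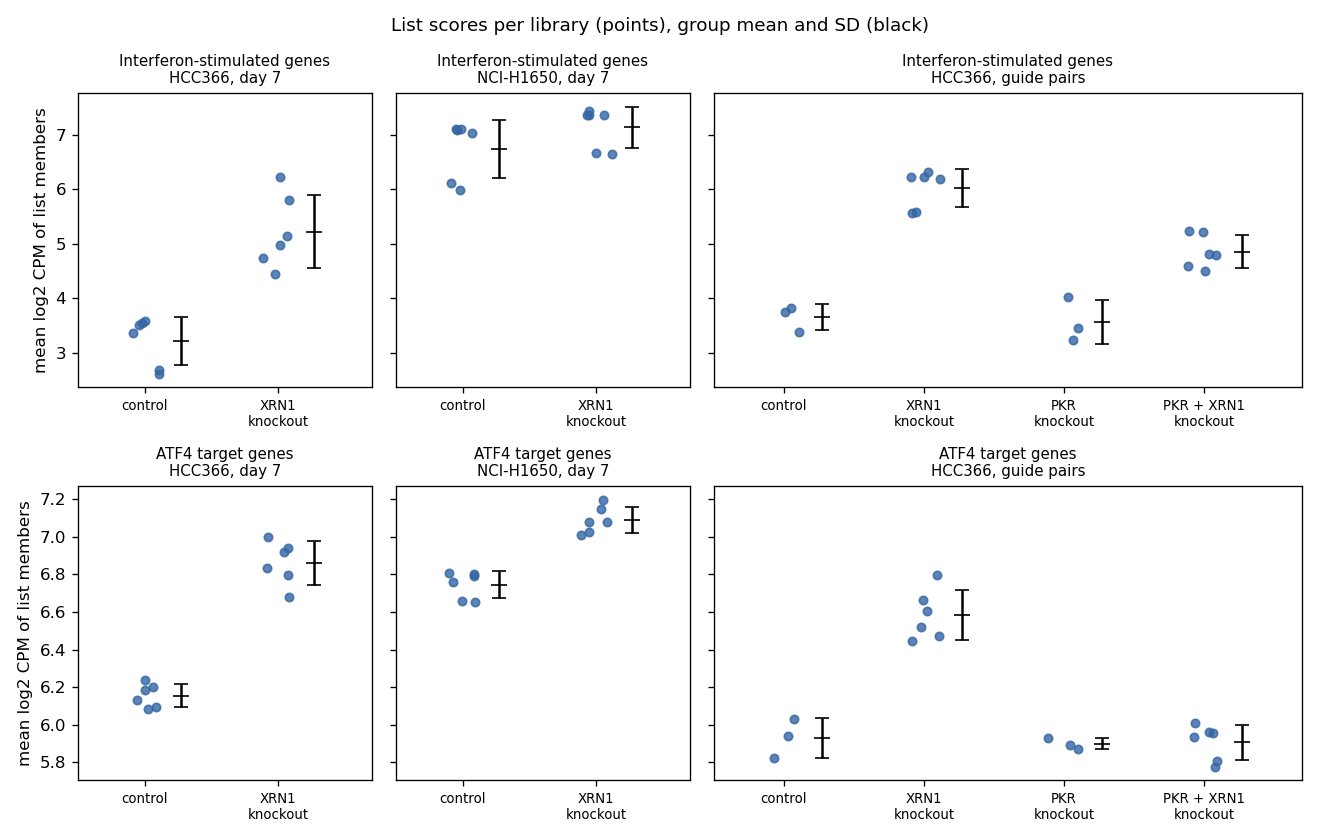
Mean log2 CPM of the interferon-stimulated (top) and ATF4 (bottom) lists in each library (points), with group mean and SD (bars), by genotype in HCC366 and NCI-H1650 at day 7 and in HCC366 with guide pairs; the panels average 48, 51 and 51 interferon-stimulated and 38, 42 and 41 ATF4 genes. In the guide-pair ATF4 panel the 6 XRN1 knockout libraries lie above those of the other genotypes, and in the interferon panel the 6 libraries lacking PKR and XRN1 lie between XRN1 knockout and control.

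In HCC366 cells with guide pairs and intact PKR, XRN1 knockout gave the day-7 pattern again. Interferon-stimulated genes rose in 49 of 51 cases and 1 fell (median 2.32, camera adjusted p = 2.39e-24, adjusted p = 0.119 with an estimated correlation). HELZ2 rose from 91.8 ± 17.9 (n = 3) to 1348 ± 311 CPM (n = 6; log2 3.88, SE 0.20, adjusted p = 7.23e-14) and IFIH1 (MDA5), a sensor of long double-stranded RNA, from 63.7 ± 12.2 to 438 ± 85.3 CPM. All 4 tested interferon genes rose, IFNB1 from 0.0771 ± 0.0339 to 3.80 ± 1.09 CPM. RNA sensing genes rose in 16 of 21 cases (median 0.80, camera adjusted p = 3.85e-06, adjusted p = 0.108 with an estimated correlation) and NF-kB genes in 26 of 28 (median 1.26, camera adjusted p = 2.23e-16, adjusted p = 0.0739 with an estimated correlation). ATF4 genes rose in 26 of 41 cases and 6 fell (median 0.46, camera adjusted p = 0.000139, adjusted p = 0.252 with an estimated correlation), with ATF3 up from 25.1 ± 2.19 to 330 ± 75.0 CPM and SESN2, a stress-induced mTORC1 inhibitor, from 24.8 ± 2.97 to 147 ± 23.0 CPM. NMD-sensitive transcripts rose in 20 of 22 (median 0.94, camera adjusted p = 2.23e-16, adjusted p = 0.000344 with an estimated correlation), including GADD45A, a growth arrest gene (2.92, SE 0.11). Immediate-early genes rose in 24 of 33 (median 0.70, adjusted p = 0.108 with an estimated correlation) and p53 targets in 13 of 23 (median 0.37, adjusted p = 0.108 with an estimated correlation).

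Several gene lists fell in this set. Cholesterol synthesis genes fell in 21 of 23 cases (median -0.91, camera adjusted p = 5.06e-16, adjusted p = 0.0739 with an estimated correlation), with SREBF2, the transcription factor of the pathway, from 195 ± 12 to 87.3 ± 5.01 CPM. By the naming rule the lowest gene was SCD, a fatty acid desaturase outside the list (log2 -2.21, SE 0.16). ER chaperones fell in 17 of 20 (median -0.55, camera adjusted p = 2.09e-07, adjusted p = 0.0918 with an estimated correlation), such as HSP90B1 (GRP94; -1.02, SE 0.057). Cell cycle genes fell in 34 of 35 (median -0.72, adjusted p = 0.119 with an estimated correlation), ribosomal protein mRNAs in 73 of 73 (median -0.66, adjusted p = 0.0977 with an estimated correlation), mitochondrially encoded genes in 13 of 13 (median -0.83, adjusted p = 0.108 with an estimated correlation) and histones in 16 of 21 (median -0.69, adjusted p = 0.211 with an estimated correlation). Lung epithelial markers fell in 4 of 9 (camera adjusted p = 0.0446, adjusted p = 0.17 with an estimated correlation), KRT8 among them (-1.06, SE 0.065). Of 17212 genes 10477 passed, 5843 higher and 4634 lower (5994 and 2188 on the TPM scale), with 2626 at least 2-fold higher and 330 at least 2-fold lower. Across 14517 genes these fold changes correlated with those at day 7 with r = 0.932 and rho = 0.909, and 3636 genes were higher in both against 1351 for independent lists.

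In the PKR knockout background, XRN1 loss still raised interferon-stimulated genes, by less, and did not shift the ATF4 list. Of 51 interferon-stimulated genes 43 rose and none fell (median 1.13, camera adjusted p = 4.2e-15, adjusted p = 0.333 with an estimated correlation), with HELZ2 at 89.8 ± 20.6 (n = 3) and 465 ± 68.2 CPM (n = 6; log2 2.37, SE 0.19). Of the 4 interferon genes 1, IFNL3, passed, with a near-zero control level, while IFNB1 was 0.172 ± 0.0872 and 0.241 ± 0.115 CPM. RNA sensing genes rose in 12 of 21 (median 0.50, camera adjusted p = 6.03e-05, adjusted p = 0.305 with an estimated correlation) and NF-kB genes in 20 of 28 (median 0.63, camera adjusted p = 1.69e-06, adjusted p = 0.333 with an estimated correlation), including IL1B from 36.5 ± 3.04 to 108 ± 7.81 CPM. In the ATF4 list 8 rose and 13 fell of 41 (median -0.033, mean 0.029, median 0.22 on the TPM scale; camera adjusted p = 0.432). Among them DDIT4, an mTORC1 inhibitor, rose by 1.20 (SE 0.12) and PSAT1, a serine synthesis enzyme, fell by 0.58 (SE 0.056). NMD-sensitive transcripts rose in 17 of 22 and none fell (median 0.61, camera adjusted p = 4.05e-12, adjusted p = 0.00171 with an estimated correlation), and NMD factors in 8 of 14 (camera adjusted p = 0.00715, adjusted p = 0.333 with an estimated correlation), with SMG1, the kinase of UPF1, up by 0.94 (SE 0.054). Hypoxia and glycolysis genes rose in 9 of 18 (median 0.30, camera adjusted p = 0.00196, adjusted p = 0.104 with an estimated correlation), VEGFA from 80.0 ± 8.10 to 199 ± 14.5 CPM. TRPV1, a cation channel, had the highest fold change by the naming rule (6.89 ± 0.917 to 66.5 ± 3.62 CPM; log2 3.28, SE 0.087, adjusted p = 2.25e-19).

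Ribosomal protein mRNAs fell in 73 of 73 cases with PKR knocked out (median -0.44, -0.084 on the TPM scale; camera adjusted p = 2.29e-28, adjusted p = 0.24 with an estimated correlation), RPS2 by 0.69 (SE 0.048). Cell cycle genes fell in 27 of 35 (median -0.36, -0.021 on the TPM scale; camera adjusted p = 4.62e-09, adjusted p = 0.333 with an estimated correlation) and histones in 17 of 21 (median -0.46, -0.118 on the TPM scale; adjusted p = 0.333 with an estimated correlation). Cholesterol synthesis genes fell in 16 of 23 (median -0.33, 0.020 on the TPM scale; camera adjusted p = 8.01e-05, adjusted p = 0.333 with an estimated correlation) and mitochondrially encoded genes in 11 of 13 (median -0.26, 0.072 on the TPM scale; camera adjusted p = 0.00367, adjusted p = 0.458 with an estimated correlation). Of 17212 genes 7041 passed, 3666 higher and 3375 lower (6906 and 274 on the TPM scale, where the median of all genes was 0.269). Fold changes with and without PKR correlated across 17212 genes with r = 0.459 and rho = 0.56.

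PKR knockout alone left few calls. By edgeR 1 gene passed, EIF2AK2, while 590 had an unadjusted p under 0.05 and DESeq2 called 4. Leaving out 1 library at a time gave 0 to 2 genes, and EIF2AK2 was not past the threshold in 9 of 18 such fits. These left out any replicate of the PKR knockout, replicate 2 or 3 of the control, replicate 2 or 3 of XRN1 guide 1 with PKR intact, or replicate 3 of either XRN1 guide with PKR knocked out (adjusted p up to 0.472, log2 fold change between -0.751 and -0.654 over the 18). Interferon-stimulated genes had a median of -0.031 (camera adjusted p = 0.346) and ATF4 genes one of -0.030 (camera adjusted p = 0.182). Cholesterol synthesis genes and immune or endothelial markers passed the list test (medians 0.057 and -0.35, camera adjusted p = 0.0176 each), with no member past the threshold by edgeR in either (adjusted p = 0.89 and 0.286 with an estimated correlation). The cholesterol call was lost without replicate 2 of the PKR knockout or replicate 1 or 2 of the control (camera adjusted p = 0.417, 0.216 and 0.0753). Interferon-stimulated genes gained one, as lower, without the first or the second of these libraries (median -0.235 and -0.122, camera adjusted p at most 6.4e-05), and ATF4 genes did so without the second (median -0.068, camera adjusted p = 0.00154).

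The dependence of the XRN1 effect on PKR was tested as the difference of the effects. It was lower with PKR knocked out for 37 of 51 interferon-stimulated genes and higher for none (median difference -1.11, camera adjusted p = 1.68e-14, adjusted p = 0.216 with an estimated correlation), as for IFIT2, an antiviral effector (-1.95, SE 0.25). For ATF4 genes it was lower for 23 of 41 and higher for 3 (median -0.41, camera adjusted p = 2.48e-12, adjusted p = 0.0985 with an estimated correlation). ATF3 was 21.3 ± 2.07 CPM (n = 3) in PKR knockout and 27.6 ± 2.66 CPM (n = 6) in PKR and XRN1 knockout libraries, a difference of effects of -3.35 (SE 0.21, adjusted p = 6.82e-11), and PPP1R15A gave -1.84 (SE 0.11). NF-kB genes had a lower effect for 19 of 28 (median -0.72, adjusted p = 0.0757 with an estimated correlation), IRF1 by -1.70 (SE 0.13). Immediate-early genes did for 17 of 33 (median -0.42, adjusted p = 0.116 with an estimated correlation), with EGR1, a growth factor-induced transcription factor, at -4.57 (SE 0.39). NMD-sensitive transcripts did for 10 of 22 (median -0.21, -0.041 on the TPM scale; camera adjusted p = 2.33e-07, adjusted p = 0.0121 with an estimated correlation), led by GADD45A (-2.37, SE 0.14) and GADD45B (-1.87, SE 0.11), and p53 targets for 9 of 23 (median -0.36, adjusted p = 0.0804 with an estimated correlation). RNA sensing genes did for 11 of 21 (median -0.44, adjusted p = 0.233 with an estimated correlation).

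The effect was higher with PKR knocked out for 12 of 18 hypoxia and glycolysis genes (median 0.52, camera adjusted p = 6.34e-07, adjusted p = 0.0114 with an estimated correlation), LDHA, lactate dehydrogenase A, being 1153 ± 140.0 CPM after XRN1 knockout and 2522 ± 141 CPM when PKR was lost as well (n = 6 each; difference of effects 1.02, SE 0.11). It was also higher for 20 of 23 cholesterol synthesis genes (median 0.58, adjusted p = 0.0757 with an estimated correlation), 15 of 20 ER chaperones (median 0.47, adjusted p = 0.0757 with an estimated correlation), 22 of 35 cell cycle genes (median 0.35, adjusted p = 0.309 with an estimated correlation), 34 of 73 ribosomal protein genes (median 0.24, adjusted p = 0.328 with an estimated correlation) and 12 of 13 mitochondrially encoded genes (median 0.56, adjusted p = 0.173 with an estimated correlation). In all, 5282 genes differed, 2670 higher and 2612 lower (2991 and 1451 on the TPM scale), and 3241 with XRN1 guide 1 alone. Of 1500 genes that were at least 2-fold higher in HCC366 at day 7 and were tested with guide pairs, 1436 were higher with PKR intact and 856 with PKR knocked out, and the effect was lower with PKR knocked out for 724 (48.3%) and higher for 75. Their median log2 fold change was 1.72 with PKR intact and 0.83 without.

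**Figure D2:**
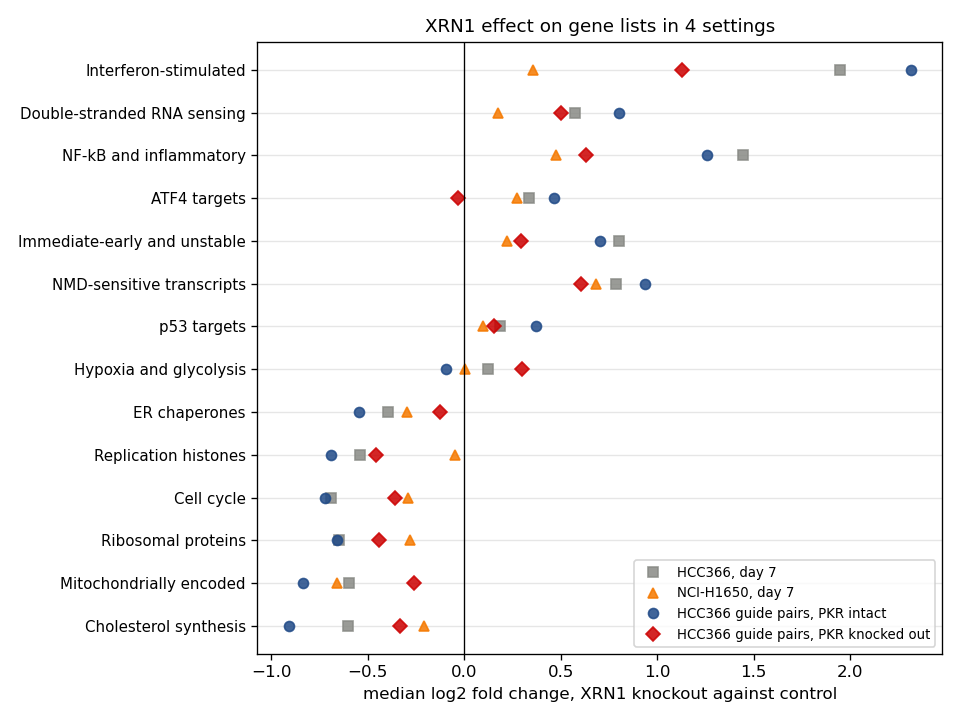
Median log2 fold change of the tested members of 14 gene lists, XRN1 knockout against control, in HCC366 at day 7 (squares), NCI-H1650 at day 7 (triangles) and HCC366 guide pairs with PKR intact (circles) or knocked out (diamonds). The interferon-stimulated medians are 1.95, 0.35, 2.32 and 1.13, and the ATF4 medians 0.34, 0.28, 0.46 and -0.033 (0.22 on the TPM scale).

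Among XRN1 knockout libraries, cells that also lacked PKR differed from PKR-intact cells in 9603 genes, 4696 higher and 4907 lower (5288 and 2509 on the TPM scale; 6155 with XRN1 guide 1 alone). Interferon-stimulated genes were lower for 44 of 51 (median -1.09, camera adjusted p = 3.97e-15, adjusted p = 0.223 with an estimated correlation) and ATF4 genes for 28 of 41 (median -0.47, camera adjusted p = 3.5e-12, adjusted p = 0.0961 with an estimated correlation). DNAH3, at 35.6 ± 8.65 CPM with PKR intact, was 0.920 ± 0.266 CPM without (n = 6 each; log2 -5.26, SE 0.18, adjusted p = 4.58e-17), close to the 0.579 ± 0.0731 CPM of controls (n = 3), and NID1 went from 19.3 ± 2.94 to 0.298 ± 0.139 CPM. STC1, a secreted hypoxia-responsive hormone, was higher (1.56, SE 0.082).

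The 2 XRN1 guides were compared within each line. By edgeR 0 genes differed between them in either line, with 90 genes in HCC366 and 146 in H1650 at an unadjusted p under 0.05 and 0 in each by DESeq2. With no filter 21 and 31 genes differed by edgeR. In simulated counts this comparison recovered 16.4% of 1.5-fold and 53.7% of 2-fold changes in HCC366 and 34.3% and 67.2% in H1650, so small differences could be missed. The control guides also differed in 0 genes by edgeR, with 125 and 389 at an unadjusted p under 0.05 and 0 and 2 by DESeq2 (28 and 55 by edgeR with no filter). Against separate controls the guides' fold changes correlated with r = 0.929 in HCC366 (14420 genes) and r = 0.704 in H1650 (16341 genes).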

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

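The tests of the NMD-sensitive list, of matched lists for the difference with PKR and of PKR loss alone in this part were chosen after the results were seen, as were the slopes over well-counted pseudogenes and on the TPM scale, the comparison of the ATF4 and interferon slopes, the splits within numbers and the bound used for shared reads.

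Libraries that stood apart from their group were few. Of 120 groups of values tested, 6 held such a library, and chance gives about 1 in 20. The guide-pair control and PKR knockout groups, with 3 libraries each, were too small for this check and were left out. A library with both knockouts (XRN1 guide 2, replicate 3) had a total of 17.0 M counts (M, 1e6), the others 18.1 to 18.7 M. A library of XRN1 knockout with PKR intact (guide 2, replicate 1) had a mean fragment length of 262 bases, the others 282 to 290, and a mean log2 CPM of 6.857 over ER chaperones, the others 6.961 to 7.011. The ribosomal RNA share was 0.022% in H1650 XRN1 knockout guide 1 replicate 2 (others 0.002% to 0.007%), 0.309% in the H1650 Chr2.2 control replicate 3 (others 0.004% to 0.01%), and 0.05% in XRN1 knockout with PKR intact, guide 1 replicate 2 (others 0.007% to 0.018%).

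The XRN1 effect differed between the lines, by the test of the difference, for 4221 genes. Medians of the difference (H1650 minus HCC366) were -1.63 for interferon-stimulated genes, -0.467 for RNA sensing, -0.975 for NF-kB, -0.163 for ATF4, -0.217 for NMD-sensitive transcripts and -0.593 for immediate-early genes. They were 0.47 for the cell cycle, 0.516 for cholesterol synthesis, 0.394 for ribosomal proteins and 0.605 for replication histones. Within HCC366 number 2 the NMD-sensitive difference (-0.145, camera adjusted p = 0.106) and the ATF4 difference (-0.0342, 0.0733) did not pass. With an estimated correlation NF-kB, immediate-early and cell cycle genes kept their call among these lists.

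The XRN1 effect also differed with PKR, for 5282 genes. Medians of the difference (PKR knocked out minus intact) were -1.11 for interferon-stimulated genes, -0.442 for RNA sensing, -0.716 for NF-kB, -0.405 for ATF4, -0.206 for NMD-sensitive transcripts (-0.0412 on the TPM scale) and -0.421 for immediate-early genes. They were 0.473 for ER chaperones, 0.35 for the cell cycle, 0.581 for cholesterol synthesis, 0.523 for hypoxia and glycolysis, 0.244 for ribosomal proteins and 0.559 for mitochondrially encoded genes. With an estimated correlation NMD-sensitive and hypoxia genes kept their call among these lists. When the replicate number was also a block, interferon-stimulated, RNA sensing, ATF4, immediate-early, ER chaperone and cholesterol genes did too (camera adjusted p 0.0483 to 0.0492). NF-kB (0.0563), cell cycle, ribosomal protein and mitochondrially encoded genes did not.

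Interferon and ATF4 genes responded less to XRN1 loss when PKR was knocked out. The median difference of effects was -1.11 for interferon genes, below all 10000 random lists matched on expression (95% between -0.0691 and 0.189, lowest -0.229), and -0.405 for ATF4 genes (95% between -0.0502 and 0.206, lowest -0.213). An error of scaling or depth moves genes of one level alike, so this argues against unequal counts or normalization as the whole cause. PKR knockout with XRN1 intact gave -0.031 for interferon genes. The difference of effects already subtracts a change made by PKR loss alone, so this value is no test of its cause. Both list calls were lost with an estimated correlation (camera adjusted p = 0.216 and 0.0985). They passed narrowly when the replicate number was also a block (0.0483 and 0.0492), a fit added after the data were seen. A pairing by number is uncertain in this set. A weaker loss of XRN1 in the PKR knockout cells that shrinks the whole response by one factor would give equal slopes of the effect without PKR on that with PKR. Bootstrap intervals of the slopes resample genes, not libraries, so they leave out spread between libraries and correlation between members. The ATF4 slope, 0.128 (95% bootstrap interval -0.0921 to 0.332), lay below the interferon slope, 0.485 (0.415 to 0.565), as on the TPM scale (0.35, 0.259 to 0.464, and 0.583, 0.542 to 0.628). As far as such intervals can tell, this argues against one such factor as the whole cause for ATF4 genes. For interferon genes it cannot be told apart. The slope over 813 pseudogenes, 0.382 (0.307 to 0.464), overlapped theirs. So did the NF-kB (0.462, 0.38 to 0.543), NMD-sensitive (0.41, 0.245 to 0.74) and cell cycle (0.552, 0.477 to 0.638) slopes. The ribosomal protein slope, 0.611 (0.573 to 0.652), lay above the interferon slope with no overlap. On the TPM scale the pseudogene slope, 0.773 (0.677 to 0.869), lay above the interferon slope, and the ribosomal (0.195) and cell cycle (0.262) slopes below it. Over 170 pseudogenes with a mean CPM of 5 or more, a level that the rise itself can bring about, the slope on the CPM scale was 0.934 (0.83 to 1.03). A weaker loss to which lists respond unequally was not tested, and XRN1 RNA does not check the loss, so a dependence on PKR stays a hypothesis beside it.

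Pseudogenes rose more often than they fell after XRN1 loss in both PKR backgrounds. In PKR knockout cells the median of pseudogene minus parent log2 fold change was 0.248 (0.176 to 0.328), above 0 in 288 of 431 pairs. The bound first set, 0.2, lies inside that interval and was replaced by 0 once the value was known. All pairs entered, and a pair also lies above 0 where the parent fell and the pseudogene fell less or stayed level. The median therefore cannot decide on reads shared with the parent. Of 98 name-matched pseudogenes that rose (median 1.39), 49 had a parent that rose, 23 one that fell and 26 one not past the threshold (median of parents 0.242). Sharing reads with a parent that fell would not raise a pseudogene, so for those 23 it is an unlikely source. For the others shared reads stay open. Pseudogenes with a mean CPM of 5 or more had a median of 0.83 (0.463 to 1.07, and 104 of 170 rose), and all 813 had one of 0.297. That mean includes XRN1 knockout libraries, so a rise can itself bring a pseudogene to this level. The test therefore cannot decide on low counts. A candidate explanation is loss of 5' to 3' decay of NMD targets, since the NMD-sensitive list rose as well (median 0.606; adjusted p = 0.00171 with an estimated correlation in PKR knockout cells), but the 2 sets were not linked gene by gene.

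Ribosomal protein mRNAs fell together in both PKR backgrounds. With PKR knocked out their median, -0.445 (-0.0838 on the TPM scale, where the median of all genes was 0.269), lay below all 10000 random lists matched on length (95% between -0.32 and -0.172, lowest -0.391) and all matched on expression (95% between -0.16 and 0.0219, lowest -0.234), which argues against transcript length and against abundance as the whole cause. A list of 25 other mRNAs known to carry a 5' terminal oligopyrimidine tract had a median of -0.386, also below all matched lists (95% between -0.227 and 0.0936, lowest -0.327). This is consistent with a response shared by such mRNAs. The call of the ribosomal list against other genes was lost with an estimated correlation (adjusted p = 0.24).

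Other splits of the same libraries were fitted, without the replicate number, to ask whether another grouping of them gives as many genes. None did for XRN1 knockout in HCC366 at day 7 (7816 genes, highest other split 0, and 1 of 100 splits gave as many, the real one) or H1650 (5780, highest other 905, 1 of 100). The same held for guide pairs with PKR intact (10477, highest other 1, 1 of 84) and PKR knocked out (7041, highest other 2, 1 of 84). It held as well for the lines' controls (13972, highest other 9294, 1 of 100) and PKR loss in XRN1 knockout cells (9603, highest other 5023, 1 of 100). For the difference between lines 4 of 100 splits gave at least 4221 genes, the highest 5053, and for that between PKR backgrounds 2 of 100 gave at least 5282, the highest 6207. In each of these highest splits 1 arm kept its real grouping (HCC366, or PKR intact), so the effect in that arm remained in the difference. PKR knockout alone (1 gene, highest other 1; 3 of 10 splits), the XRN1 guides (0 genes by edgeR and highest other 0 in each line; 10 of 10) and the control guides (0 by edgeR, highest other 0 in HCC366 and 1 in H1650; 10 of 10) had too few splits for a share under 0.05. Spread between numbers, and the XRN1 effect itself, add to the residual spread of the other splits and lower their counts. The splits therefore speak only to the grouping of these libraries. Chance differences between cultures are not excluded, since the replicates may be technical. In HCC366 at day 7, where the numbers pair the libraries, splits within numbers with the number as a block gave 9865 genes for the real split and at most 1 for the others (1 of 100 splits gave as many, the real one). Unadjusted counts and those of DESeq2 stand with these results above.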

How the results depend on the processing

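Fits within single HCC366 numbers, and the block with DESeq2 factors or an estimated correlation, were chosen after the data were seen, and the cause of the changes listed here was not tested except where fewer libraries or genes entered. Of 340 counts of genes under an alternative 302 stayed within 1.5 times, and of 12485 values of named genes 12326 kept direction and call (145 lost the call, 7 gained it, 7 turned). Of 2860 list values 2655 kept both (136 lost, 22 gained, 47 turned). DESeq2 size factors and the stricter filter kept all 13 counts within 1.5 times. Depth limits genes with low counts, which the filter removes, and IFNB1 in HCC366 was not tested at day 7.

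Counts moved as follows. With a 2-fold minimum, which only removes genes, they were 1599 (HCC366), 470 (H1650), 1195 (difference of lines), 7615 (control lines), 2956 (guide pairs, PKR intact), 1162 (PKR knocked out), 1836 (PKR loss in XRN1 knockouts), 1082 (difference with PKR) and 0 (PKR loss alone, by edgeR, with 590 at an unadjusted p under 0.05 and 4 by DESeq2 with no minimum). On log2(TPM + 1) they were 2541 (HCC366), 1338 (H1650), 632 (difference of lines), 8920 (control lines) and 2 (PKR loss alone). With XRN1 guide 1 only they were 6155 (PKR loss in XRN1 knockouts), 1780 (difference of lines) and 3241 (difference with PKR), and with number 3 only the difference of lines gave 2701. With no filter PKR loss alone gave 58, the XRN1 guides 21 (HCC366) and 31 (H1650) and the control guides 28 and 55. DESeq2 gave 4 for PKR loss alone and 2 for the H1650 control guides. Correlations across genes with a mean CPM of 10 or more were 0.711 (lines), 0.958 (HCC366 day 7 and guide pairs), 0.733 (PKR backgrounds), 0.974 (XRN1 guides, HCC366) and 0.815 (H1650).

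With the replicate block, the count for the difference of lines was 6921 and that for PKR loss alone 5, and the other 11 counts stayed within 1.5 times, as did that of HCC366 with DESeq2 factors as well. In H1650 17 of 18 same-number pairs correlated above 0.1 (lowest 0.023, median 0.31 against -0.152 for different numbers). In the guide-pair set 17 of 45 did (lowest -0.0556, median 0.0822 against -0.041). Every library correlated best with its own number, so the numbers may pair these sets too, more weakly with guide pairs. Among named genes the block added a call for XRN1 in the difference of lines and for EIF2AK2 in the difference with PKR, and it ended none. Among lists it added a call for RNA sensing in H1650 (camera adjusted p = 0.00236, 0.198 with an estimated correlation) and for NMD factors with PKR intact (0.0464, 0.135 with an estimated correlation), and changed no call of the HCC366 day-7 sets other than those given with their results.

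Of 117 list values 72 lost their call with an estimated correlation and 55 with the block as well. For interferon-stimulated genes the medians (adjusted p with an estimated correlation) were 1.95 (0.298) in HCC366, 0.355 (0.801) in H1650, -1.63 (0.22) between lines, 3.06 (0.948) in control lines, 2.32 (0.119) with PKR intact, 1.13 (0.333) with PKR knocked out, -1.09 (0.223) for PKR loss in XRN1 knockouts and -1.11 (0.216) for the difference. With the block they were lost in HCC366 (1.95, 0.169), H1650 (0.385, 0.206) and control lines (3.01, 0.252). They passed between lines (0.0299), with PKR intact (0.0113), with PKR knocked out (0.046), for PKR loss in XRN1 knockouts (0.0366) and for the difference (0.0483). For ATF4 genes they were 0.336 (0.103) in HCC366, 0.275 (0.293) in H1650, -0.163 (0.265) between lines, 0.707 (0.649) in control lines, 0.464 (0.252) with PKR intact, -0.467 (0.0961) for PKR loss in XRN1 knockouts and -0.405 (0.0985) for the difference, and with the block 0.332 (0.12), 0.268 (0.202), -0.157 (0.181), 0.745 (0.62), 0.459 (0.206) and -0.465 (0.0599) for the first 6. The ATF4 difference with PKR passed with the block and an estimated correlation (camera adjusted p = 0.0492). Within HCC366 number 2 the ATF4 difference between lines was -0.0342 (adjusted p = 0.0733).

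With PKR knocked out, 1 gene and 2 lists with a call turned on log2(TPM + 1): MT-ND1 (0.0114), cholesterol synthesis (-0.332 to 0.0195) and mitochondrially encoded genes (-0.259 to 0.0717). The other values that turned had no call before, and 1 gained one, immediate-early genes for PKR loss alone without control replicate 3 (0.0466). On log2(TPM + 1) XRN1 was -0.278 between control lines, 0.137 in HCC366 and -0.0628 for the difference of lines, and within number 1 it was 0.00965 in HCC366. The hypoxia list was -0.00872 between control lines (number 3), -0.00467 for the difference of lines (number 1) and -0.00255 in H1650 (DESeq2 factors). Mitochondrially encoded genes had differences between lines of 0.0797 (number 2), 0.0835 (number 3) and 0.0759 (both).

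Leaving out 1 library at a time gave these ranges where a call or sign changed or a called median moved by over 1.5 times. For PKR loss alone the count was 0 to 2, and medians were -0.071 to 0.0074 (ATF4), -0.0119 to 0.0568 (ER chaperones), -0.0288 to 0.066 (cell cycle), 0.0306 to 0.123 (cholesterol synthesis, not past the test without PKR knockout replicate 2 or control replicate 1 or 2, adjusted p = 0.417, 0.216 and 0.0753), -0.0366 to 0.0518 (RNA sensing), -0.0107 to 0.0394 (hypoxia), -0.122 to 0.0466 (immediate-early), -0.235 to 0.0662 (interferon, past the test without the first or second of these libraries, adjusted p at most 6.4e-05), -0.0467 to 0.0627 (mitochondrial), -0.0578 to 0.0869 (NF-kB), -0.0872 to 0.00264 (histones) and -0.0243 to 0.0559 (ribosomal). EIF2AK2 ranged from -0.751 to -0.654 there (call changed in 9 of 18 fits), and from -0.0184 to 0.116 in H1650. In the difference of lines these named genes changed call, over 24 fits: MSX2 (3.79, 1.73 to 4.01, 16 fits, lowest without HCC366 AAVS1 control replicate 3, adjusted p = 0.375), TBX3 (4.04, 3.23 to 4.27, 10 fits), GSDMC (3.76, 3.16 to 3.99, 1 fit, without that library) and CSF3 (-4.32, -4.58 to -4.06, 1 fit, without H1650 Chr2.2 control replicate 1). XRN1 between control lines ranged from 0.112 to 0.166 and gained a call in 3 fits. ER chaperones ranged from -0.391 to -0.337 in control lines and 0.112 to 0.186 between lines, hypoxia from -0.0432 to 0.0474 and mitochondrial genes from -0.21 to 0.111 between lines. In H1650 they were 0.0801 to 0.19 (RNA sensing), 0.122 to 0.271 (immediate-early, no call changed, lowest without AAVS1 control replicate 2), -0.041 to 0.0997 (hypoxia), 0.233 to 0.454 (interferon, lowest without the Chr2.2 control replicate 3) and -0.098 to 0.0247 (histones), and hypoxia with PKR intact -0.137 to 0.0101. The guide comparisons in H1650 gave 0 to 1 gene by edgeR.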

Other observations

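The comparison of HCC366 XRN1 knockouts with H1650 controls in this part was chosen after the data were seen.

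Genes were counted by type, with no test of a difference between types. With PKR intact 34.6% of protein-coding genes rose and 31.8% fell after XRN1 loss, and with PKR knocked out 23% and 23.5%. With PKR intact 327 of 813 pseudogenes rose and 60 fell (median 0.499), and with PKR knocked out 210 rose and 28 fell (median 0.297), and the effect was lower without PKR for 55 and higher for 47. Of 2208 long noncoding RNAs 664 rose and 177 fell with PKR intact (median 0.283), and 253 rose and 99 fell without PKR (median 0.0188), and the effect was lower without PKR for 257 and higher for 74. In H1650 194 of 645 pseudogenes rose and 25 fell. The pseudogene share of all counts was 0.357% ± 0.00577 in guide-pair controls (SD, n = 3) and 0.617% ± 0.0197 after XRN1 knockout (n = 6), and 0.35% ± 0.01 and 0.602% ± 0.00753 in the PKR knockout background.

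Of 52 interferon-stimulated genes 39 were lower and 5 higher in HCC366 XRN1 knockouts than in H1650 controls (median -1.28), though the list did not pass against other genes (camera adjusted p = 0.12; adjusted p = 0.879 with an estimated correlation). Of 1929 genes higher after XRN1 knockout in both lines at day 7, 1857 were higher with guide pairs and PKR intact and 1406 with PKR knocked out. The effect was lower without PKR for 700 (36.3%) and higher for 169.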
